A study of Mus musculus with 2 samples.

How the data were processed

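CD4 T cells were sorted from visceral adipose tissue and spleen of C57BL/6 Foxp3.Cre-YFP mice with or without Bmal1 in Tregs, at zeitgeber times 0 and 12, per the labels' protocols. The cells were labelled with hashtag antibodies, pooled and run as single-cell 3′ RNA-seq (10x Genomics), which gave 2 libraries, 1 of gene expression and 1 of hashtags. The deposited expression values are raw UMI counts per gene and barcode, limited by the authors to called cells and not normalised. The matrix header names cellranger 4.0.0, while the submitters' processing notes name Cell Ranger 6.0, Seurat 3 and the mm10 genome. The conflict between these versions could not be settled from the values. The deposited hashtag values are raw counts per tag and barcode for 149999 barcodes, and the tool that made them is not stated in the sources used here. Of 55487 gene IDs, 54349 were found in the reference names and 52570 carried the same symbol. For the 114 symbols shared by more than 1 ID, genes were kept apart by ID.

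The hashtag features are numbered 1 to 10, with a further entry for unmatched reads. The 6 hashtags with more than 1000 counts over all barcodes were used. Their names do not give tissue, genotype or time, and no hashtag was assigned to any of these from its values or its order. The planned tests between tissues, genotypes and times, which needed that assignment, were therefore not run. The fallback fixed before the data were examined was followed instead, in which cell classes are described and each hashtag is given its own values. The comparisons of cell classes within hashtags extend a planned comparison of clock genes between Treg-like and other T cells, and those between Treg-like clusters and against naive cells were added after the cells had been clustered.

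Hashtags were called with HTODemux (Seurat 5.3.0, R 4.3.3) at a positive quantile of 0.99 after centred log-ratio normalisation of the 22952 expression barcodes present in the hashtag library. This gave 14879 singlets (64.8%), 5804 doublets (25.3%) and 2269 barcodes with no call (9.88%). Barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept, 21236 in all, of which 13599 were singlets. Pairs of cells with the same hashtag are not seen by this method and were estimated at 1302 of the singlets (8.75%).

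Clustering used scanpy 1.11.5 in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes without T cell receptor variable genes were chosen, and 30 principal components, 15 neighbours and Leiden resolution 1 were used. A cluster was named from 21 marker classes fixed in advance when at least 3 of its markers were at 10 CPM or more and 1.5-fold above the other cells and a marker was among its 20 leading genes; a Treg-like name also needed raised Foxp3. Ties and clusters with more of these markers of another class than of their own among the 10 leading genes stayed without a name. A cluster counted as T cells when it had no name of another cell type and its level of 4 T cell genes was at least 50% of that of the median cluster. A Treg-like cluster with at least 5 raised VAT Treg markers was called VAT-Treg-like. A cluster that met the rules of both the Treg-like and the interferon-responding class was split again at resolution 0.4, a step chosen after the clusters were seen. T cell clusters outside the Treg-like ones formed the Tconv-like class, which includes clusters without a name, proliferating cells and a cluster of low UMI counts. Shares carry exact Clopper-Pearson intervals at 95%. Levels are CPM, the UMI count of a gene scaled by the UMI total of the summed class, with exact Poisson intervals.

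For each comparison of classes, UMI counts were summed per hashtag and class, using hashtags with at least 50 cells on each side. The log2 ratio of CPM with a prior count of 0.5 was taken within each hashtag, and the median and range over hashtags are given. Markers of the Treg-like, VAT-Treg-like, naive CD4-like and Th1-like classes, and leading genes of the Treg-like and naive CD4-like clusters, were left out of results. Leading genes of other Tconv-like clusters were not left out. Clusters were built on variable genes of the same cells, so genes that vary with those left out can still restate the clustering in every comparison. The 21 gene lists fixed before the files were opened were read at members with 10 CPM or more. Each list's median was placed among 10000 random lists of equal size matched on expression in 20 bins, with a 95% interval from 200 Poisson draws. A list is called higher or lower when it lies below percentile 2.5 or above percentile 97.5. Genes named are the clock members at 10 CPM or more, and from each other list called, up to 3 members with the largest change among those that moved the same way in all hashtags. Some genes that meet this rule are not reported here, although they stay in the list medians and counts. Cluster leaders, Npas2 and Nr1d1 stand outside that rule, and were chosen after their values were seen. The planned rule for the tests that were not run named no genes. Figures were drawn with matplotlib 3.10.9.

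The ratios were tested on simulated data for the VAT-Treg-like against Tconv-like comparison, with 4 hashtags and 7750 genes. Both sides were given the same depth, a fixed share of each hashtag's UMIs, whereas the real Tconv-like class was deeper. Counts held Poisson error alone, with no other spread between hashtags, so the intervals were tested against counting error only. A true log2 change of 1 gave the right sign in all 4 hashtags for 100% of genes, and 94% of intervals held the truth. A change of 0.585 did so for 94% of genes, and a change of -0.585 for 88%. Of 1000 unchanged genes 12.7% had the same sign in all 4 hashtags, so a shared direction alone is weak evidence for a single gene. A class of 448 VAT-Treg-like cells, the smallest used in that comparison, held 1626127 UMIs, which gave Arntl 27 UMIs and an interval from 10.9 to 24.2 CPM.

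The alternatives tried were a hashtag rule (at least 80% of a cell's hashtag counts from 1 tag, and at least 10 counts), a stricter cell filter (at least 1000 genes and under 5% mitochondrial counts), Tregs taken as T cells with a Foxp3 UMI, Leiden resolutions 0.5 and 1.5, counts pooled over hashtags, removal of the 10% of cells with the most UMIs, other definitions of the Tconv-like class, each of the other Treg-like clusters alone, and leaving out each hashtag. Doublets and barcodes without a call were left out of all comparisons because such cells cannot be placed in a single hashtag, and hashtags 7 to 10 because they had too few counts.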

Results

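The study compared CD4 T cells of mice whose regulatory T cells (Tregs) kept or lacked Bmal1, the transcription factor encoded by Arntl that drives the core circadian clock. Cells were sorted from visceral adipose tissue (VAT) and spleen at zeitgeber time (hours after lights on) 0 and 12, tagged with hashtag antibodies and pooled. Per the labels, 34000 VAT and 32000 splenic cells were sorted. The 2 tissues, 2 genotypes and 2 times make 8 combinations, but the hashtags are named by number alone and only 6 of them, numbers 1 to 6, carried more than 1000 counts. No hashtag could therefore be assigned to a tissue, genotype or time, and no comparison between these was made. Cell classes were compared within each hashtag instead, and each hashtag has its own values. Hashtags of unknown origin are not replicates, so no test across them was run. In hashtags of mice lacking Bmal1 in Tregs, Treg-like cells would lack it while other T cells kept it. Clock gene ratios between Treg-like and other T cells can therefore hold genotype as well as cell class.

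The expression library held 22960 barcodes, 55487 genes and 96923402 UMIs, with a median of 3469 UMIs and 1349 genes per barcode. After the cell filter, 13599 cells with a single hashtag and 48738657 UMIs were kept. Hashtags 1 to 6 held 2974, 1613, 2058, 1360, 3488 and 2106 cells, in that order. Their UMI totals were 10059797, 5666259, 7104496, 4531290, 12866268 and 8510547, and the median UMIs per cell ran from 2820 in hashtag 1 to 3773 in hashtag 6. Shares and levels carry exact 95% intervals and list medians 95% intervals from Poisson draws, while brackets after the log2 ratio of a single gene are ranges over hashtags. Intervals cover counting error only, not differences between mice or sorts.

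T cells made up 12856 of the 13599 cells. The most abundant cluster was naive CD4-like (2858 cells), led by Dapl1, Igfbp4, Satb1 and the lymph node homing receptor Ccr7. Th1-like cells fell into 3 clusters of 983, 1596 and 527 cells, of which the smallest was led by Gzmk and Eomes and the others by Ly6c2, Ifng or Il18r1. Smaller T cell clusters were Tfh-like (352 cells; Cxcr5, Pdcd1 and Il21), NKT or innate-like (356 cells; Klrd1 and Gzma), proliferating (209 cells; Mki67 and Top2a) and interferon-responding (102 cells; Ifit1 and Isg15). A cluster of 347 cells without a name under the marker rule was led by Csf2, Tmem176a, Tmem176b, Il5 and Ccr6. The 743 other cells included macrophage-like (236 cells; C1qa and Vcam1), B-like (135 cells) and stromal-like cells (24 and 20 cells), and a cluster of 273 cells led by the vascular genes Gpihbp1, Cldn5 and Cdh5.

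Treg-like clusters held 3224 of the 12856 T cells, 25.1% (24.3 to 25.8), and fell into a VAT-Treg-like class of 2360 cells (18.4%, 17.7 to 19.0) and other Treg-like cells (864 cells, 6.72%, 6.29 to 7.17). VAT-Treg-like is a name from markers, not a tissue of origin. It covered cluster 12 (1729 cells), in which 9 of 10 VAT Treg markers were raised, and cluster 17 (631 cells), in which 6 of 10 were raised. Cluster 12 was led by Areg, which encodes the tissue repair factor amphiregulin, by Il1rl1, which encodes the interleukin-33 receptor ST2, and by Klrg1. Cluster 17 was led by Ccl4, Cyp11a1, Gzmb and the anti-inflammatory cytokine gene Il10. The other Treg-like cells fell into a larger cluster (505 cells), led by the interferon-induced genes Iigp1, Gbp2, Gm12250 and Igtp beside Gpr83 and Izumo1r, with 3 of 8 Treg markers raised, and a smaller one (359 cells), led by Tnfrsf9, Tnfrsf4 and Ikzf2, with 6 of 8 raised. The interferon-responding cluster, placed in the Tconv-like class, had 4 of 8 Treg markers raised, more than that larger cluster. A UMI of Foxp3, the defining Treg transcription factor, was found in 18.6% of VAT-Treg-like cells (17.1 to 20.3; median 3047 UMIs) and in 12.2% of other Treg-like cells (10.1 to 14.5; median 3364.5 UMIs). In naive CD4-like cells, which should lack it, the share was 0.700% (0.428 to 1.08; median 3958 UMIs). Within the Tconv-like class it reached 12% of proliferating cells (7.89 to 17.2; median 9132 UMIs) and 12.7% of interferon-responding cells (6.96 to 20.8; median 3357.5 UMIs). Both are as high as in other Treg-like cells, though proliferating cells had far more UMIs. In clusters outside the T cells the share was 3.81% of macrophage-like (1.76 to 7.12), 5.19% of B-like (2.11 to 10.4) and 7.69% of erythroid-like cells (1.62 to 20.9; 39 cells). In the larger group of stromal-like cells it was 8.33% (1.03 to 27; median 11602 UMIs). These intervals in part overlap that of other Treg-like cells.

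Hashtags differed in their Treg classes. VAT-Treg-like cells were 27.4%, 39.3%, 23.3% and 39.98% of the T cells in hashtags 1, 2, 3 and 4, but only 2 cells each in hashtags 5 and 6 (0.0606% and 0.103%). Other Treg-like cells were 2.11%, 0.648%, 1.51%, 1.07%, 14.8% and 13.6% of T cells in hashtags 1 to 6. Naive CD4-like cells of the main naive cluster were 41.7% and 47.6% of all cells in hashtags 5 and 6 and 3.40%, 3.29%, 7.92% and 6.32% in hashtags 1 to 4. The Th1-like cluster led by Ifng reached 15%, 14.3%, 8.11% and 10.1% in hashtags 1 to 4 and 0.0475% in hashtag 6, while no cell of hashtag 5 fell in it. A sort can set such shares. With Tregs taken as cells with a Foxp3 UMI, they were 5.97% of all T cells.

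**Figure D1:**
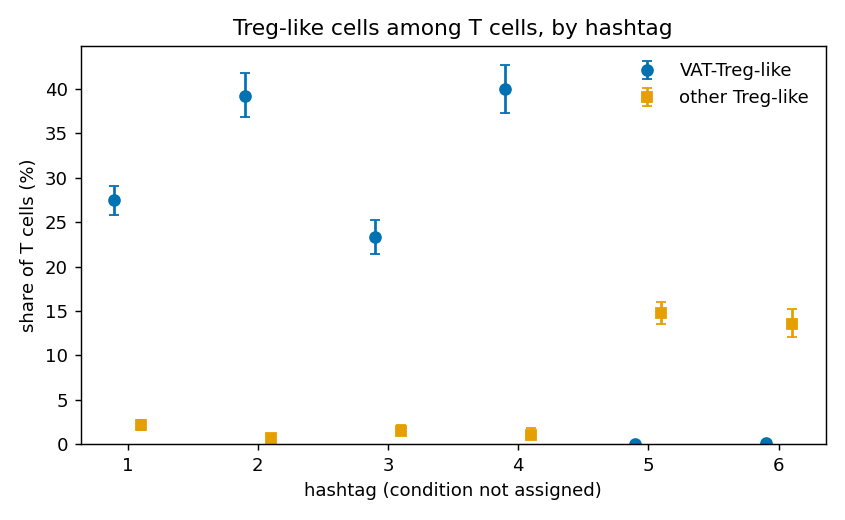
Share of T cells (percent, y axis) that was VAT-Treg-like or other Treg-like in each hashtag (x axis), with exact 95% intervals. VAT-Treg-like shares ran from 23.3% to 39.98% in hashtags 1 to 4, and other Treg-like shares were 14.8% and 13.6% in hashtags 5 and 6.

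The targeted gene, Arntl, was read in every hashtag and class with enough cells. In VAT-Treg-like cells Arntl was at 20.9 CPM (15.8 to 27.1), 24.5 (18.4 to 31.9), 16.6 (10.9 to 24.2) and 24.9 (18.2 to 33.4) in hashtags 1 to 4. Their intervals overlapped, so hashtags 1 to 4 were not separable by Arntl in VAT-Treg-like cells at this depth. In Tconv-like cells, the T cells outside the Treg-like clusters, it was at 19.7 (16.4 to 23.5), 21.3 (16.2 to 27.4), 17.8 (14.1 to 22.1), 17.9 (12.9 to 24.2), 13.1 (11 to 15.5) and 14.1 CPM (11.4 to 17.2) in hashtags 1 to 6. Hashtag 5 thus lay below hashtags 1 and 2, but its Tconv-like class had another make-up, with 1453 of 2810 cells in the main naive cluster, where Arntl was low, against 101 of 2000 and 53 of 928. Other Treg-like cells of hashtags 1, 5 and 6 had 19.2, 19.9 and 16.4 CPM. The library reads 3′ ends and the deleted part of the gene is not given in the sources used here, so reads outside that part check nothing about the deletion.

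Other clock genes did differ between hashtags in VAT-Treg-like cells. Npas2, a paralog of Clock that pairs with Bmal1, was at 1.83 CPM (0.595 to 4.28), 20.5 (15 to 27.3), 0.615 (0.0156 to 3.43) and 21.1 (14.9 to 28.9) in hashtags 1 to 4. Cry1, a repressor of the clock, was at 20.9 (15.8 to 27.1), 50.8 (41.9 to 61.0), 13.5 (8.48 to 20.5) and 61.5 CPM (50.6 to 74.1). Nr1d2, which encodes the repressor Rev-erb beta, ran the other way, at 23.1 (17.8 to 29.6), 6.24 (3.41 to 10.5), 23.4 (16.5 to 32.1) and 3.32 CPM (1.22 to 7.24). Its paralog Nr1d1 was at 10.3, 1.34, 6.76 and 3.88 CPM. Per1 varied less, between 28.1 and 38.9 CPM. In Tconv-like cells of the same hashtags Cry1 was at 18.6, 30.9, 13.8 and 23.4 CPM, Nr1d2 at 16.2, 15.6, 24.2 and 14.0, Npas2 at 0.646, 3.19, 0.888 and 2.55, and Nr1d1 at 5.66, 3.90, 6.22 and 2.98. Npas2 and Nr1d1 were chosen after their values were seen, and the hashtags are not grouped by these levels here.

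**Figure D2:**
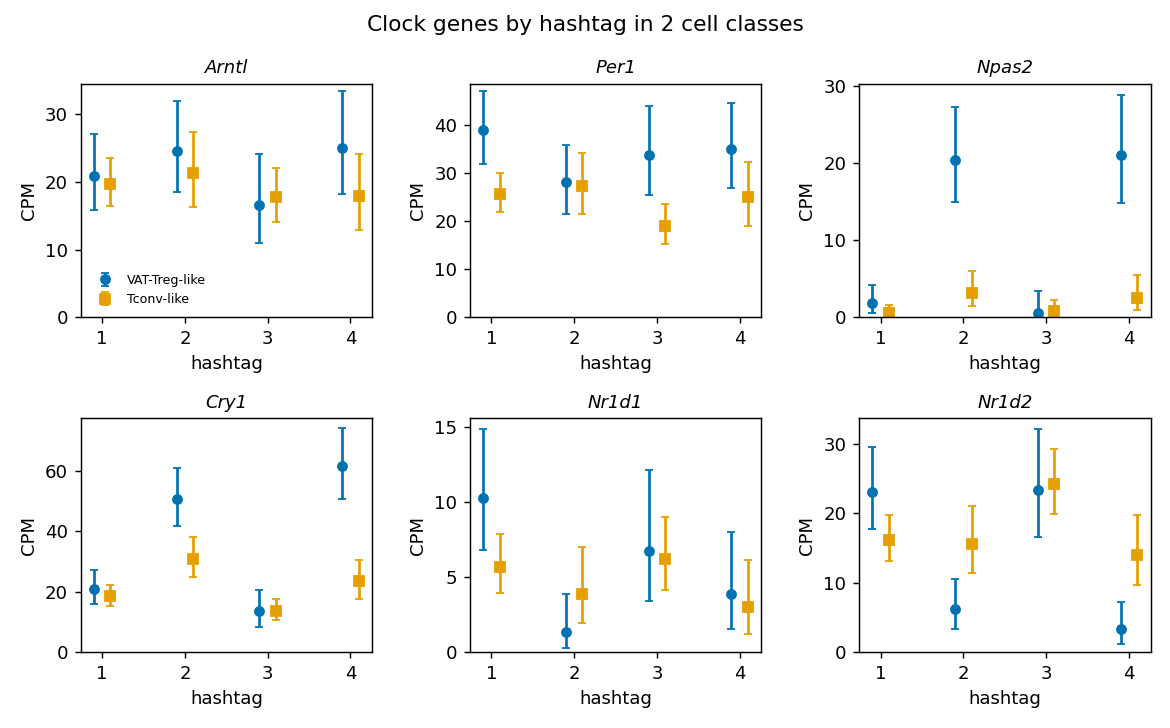
Level (CPM, y axis) of 6 clock genes in VAT-Treg-like cells (circles) and Tconv-like cells (squares) of hashtags 1 to 4 (x axis), with 95% Poisson intervals. In VAT-Treg-like cells Cry1 lay between 13.5 and 61.5 CPM and Nr1d2 between 3.32 and 23.4, while the Arntl intervals overlapped.

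How VAT-Treg-like cells differ from the Tconv-like cells tagged alongside them was read from 2356 and 5146 cells of hashtags 1 to 4 (8404015 and 15862878 UMIs; 7676 genes at 10 CPM or more, with a median log2 ratio of -0.02). Adipose Treg genes were higher in VAT-Treg-like cells. Leaving out the markers that define the classes, 9 of 10 measured members of the adipose Treg signature were higher in all 4 hashtags, with a list median of 1.48 on the log2 scale (1.31 to 1.56). The class was named for raised VAT Treg markers, so genes that vary with these markers in part restate that choice. The chemokine receptor gene Ccr1 was higher by 2.81 (range over hashtags 1.62 to 3.13; 56.3 against 6.85 CPM), Lgals3, which encodes galectin-3, by 1.91 (1.76 to 2.55) and S100a6 by 1.72 (1.53 to 1.94). T cell receptor and activation genes were also higher, 11 of 12 of them, with a median of 1.10 (1.04 to 1.20). They include the NF-kappaB inhibitors Nfkbia (1.88, range 1.46 to 2.08) and Tnfaip3 (1.43, 1.02 to 1.44) and the transcription factor gene Irf4 (1.56, 1.32 to 2.21). In the same cells, 10 of 11 measured genes of AP-1 and of dissociation or heat stress were higher in all 4 hashtags, while Hsph1 stood at 0.01. Their median was 0.88 (0.78 to 0.92), with Jun at 1.58, Jund at 1.43 and Junb at 1.27. With Tregs taken as cells with a Foxp3 UMI, the AP-1 median was 0.18. Here and below, that class holds T cells of any cluster, with 440 VAT-Treg-like, 105 other Treg-like and 223 Tconv-like cells having such a UMI. They come from any hashtag with enough cells, so this is a contrast of other cells.

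Lipid genes were higher in VAT-Treg-like cells in several lists. Plin2, which encodes a lipid droplet coat protein, was higher by 2.23 (2.06 to 2.71; 232 against 42.8 CPM). Dgat1, which encodes an enzyme of triglyceride synthesis, was higher by 1.65 (1.19 to 1.73) and the fatty acid binding protein gene Fabp5 by 1.19 (0.75 to 1.37). The lipid uptake and storage list had 6 of 10 members higher and a median of 0.28 (0.18 to 0.43), which was 0.14 with Tregs taken as cells with a Foxp3 UMI. Fatty acid and sterol synthesis had 14 of 16 higher, 12 of them in all 4 hashtags, with a median of 0.42 (0.35 to 0.58) and the sterol synthesis genes Cyp51 at 0.89 (0.50 to 1.29) and Hmgcs1 at 0.86 (0.23 to 1.14). Fatty acid oxidation had 14 of 16 higher but by less, with a median of 0.16 (0.11 to 0.29) and Etfb at 0.70 (0.58 to 0.88). Oxidative stress genes were higher in 15 of 16 cases (median 0.25, 0.18 to 0.31), among them the glutathione peroxidase genes Gpx1 (0.85) and Gpx4 (0.67). Unfolded protein response genes were higher in 11 of 13 cases (median 0.33, 0.20 to 0.38, and 0.18 without hashtag 4), with the chaperone gene Calr at 0.43 and Pdia6 at 0.40.

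Survival genes split. Bcl2, an anti-apoptotic gene, was lower by a log2 ratio of -2.11 (-2.38 to -1.79; 73.9 against 332 CPM), while the p53 targets Cdkn1a (1.89, 1.60 to 2) and Pmaip1 (1.57, 1.40 to 1.70) were higher. The apoptosis and survival list had 12 of 18 members higher and a median of 0.23 (0.15 to 0.36). Among cytokines and effector molecules, 7 of 12 were higher (median 0.31, 0.04 to 0.52, and 0.15 to 0.61 as single hashtags were left out), but the largest changes were lower, with Xcl1 at -2.81 (-3.76 to -2.23) and Il2 at -2.24 (-2.91 to -1.74). Interferon response genes were lower in 9 of 12 cases (median -0.47, -0.60 to -0.28), including Rtp4 (-1.31) and Ifi213 (-1.28), whereas Isg20 was higher (1.29). With Tregs taken as cells with a Foxp3 UMI the interferon median was 0.01. Mitochondrially encoded genes were lower in 9 of 9 cases (median -0.27, -0.37 to -0.21), such as mt-Nd2 (-0.44) and mt-Cytb (-0.42). However, the Tconv-like class includes a cluster of low UMI counts with a median mitochondrial share of 5.71%, against 2.14% in other T cells. All 13 proliferation genes were lower (median -1.85, -2.10 to -1.47; Mki67 at -2.68), but the Tconv-like class includes the proliferating cluster, and without it and a cluster of low UMI counts the median was 0.22. For Treg core genes beyond the defining markers the median was 0.45 (0.19 to 0.77), with Capg at 1.62 and Icos at -0.45. Xcl1, Rtp4, Mki67 and the clock gene Bhlhe40 were among the leading genes of Tconv-like clusters, so their lower values in part restate the clustering. The direction of the Treg core list turned to -0.02 without hashtag 1 or hashtag 3, and to -0.41 with the stricter cell filter. That filter put 66.1% of the cells of cluster 17 in a cluster named Th1-like, outside the VAT-Treg-like class.

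The lists named above as higher or lower lay outside the middle 95% of 10000 random lists matched on expression. The other lists stayed inside it. Lymphoid Treg and naive genes had a median of -0.06 (percentile 28.6), glycolysis 0.11 (91.4), nuclear oxidative phosphorylation 0.03 (55.5), homing and adhesion -0.02 (42.3), glucocorticoid response 0.18 (93.4) and exhaustion and inhibitory receptors 0.26 (93.6). The exhaustion median was -0.05 without hashtag 3. The clock list was inside it as well, with a median of 0.14 (-0.03 to 0.26, percentile 94.7), 8 of 12 measured members higher, and -0.01 without hashtag 3. Because hashtags of unknown genotype enter these ratios, they are not a difference of cell class alone. Rora and Nfil3 are also members of the clock list, but were left out in every comparison as genes that define the classes. Only a few of the others kept their direction in all 4 hashtags. Hlf, which encodes a clock output transcription factor, was higher by 1.77 (1.42 to 1.93; 26.8 against 7.30 CPM) and Per1 by 0.54 (0.04 to 0.83; 34.4 against 25.4 CPM). Bhlhe40, a repressor that feeds back on the clock, was lower at -0.61 (-1.36 to -0.40; 39.7 against 74.9 CPM). Arntl had a median of 0.15 (-0.08 to 0.48), higher in 3 of 4 hashtags, and Clock -0.10 (-0.29 to 0.10). Nr1d2 ranged from -1.98 to 0.52 and Cry1 from 0.00 to 1.39. Csnk1e (0.58), Dbp (0.14), Csnk1d (0.01) and Tef (-0.30) changed sign between hashtags.

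**Figure D3:**
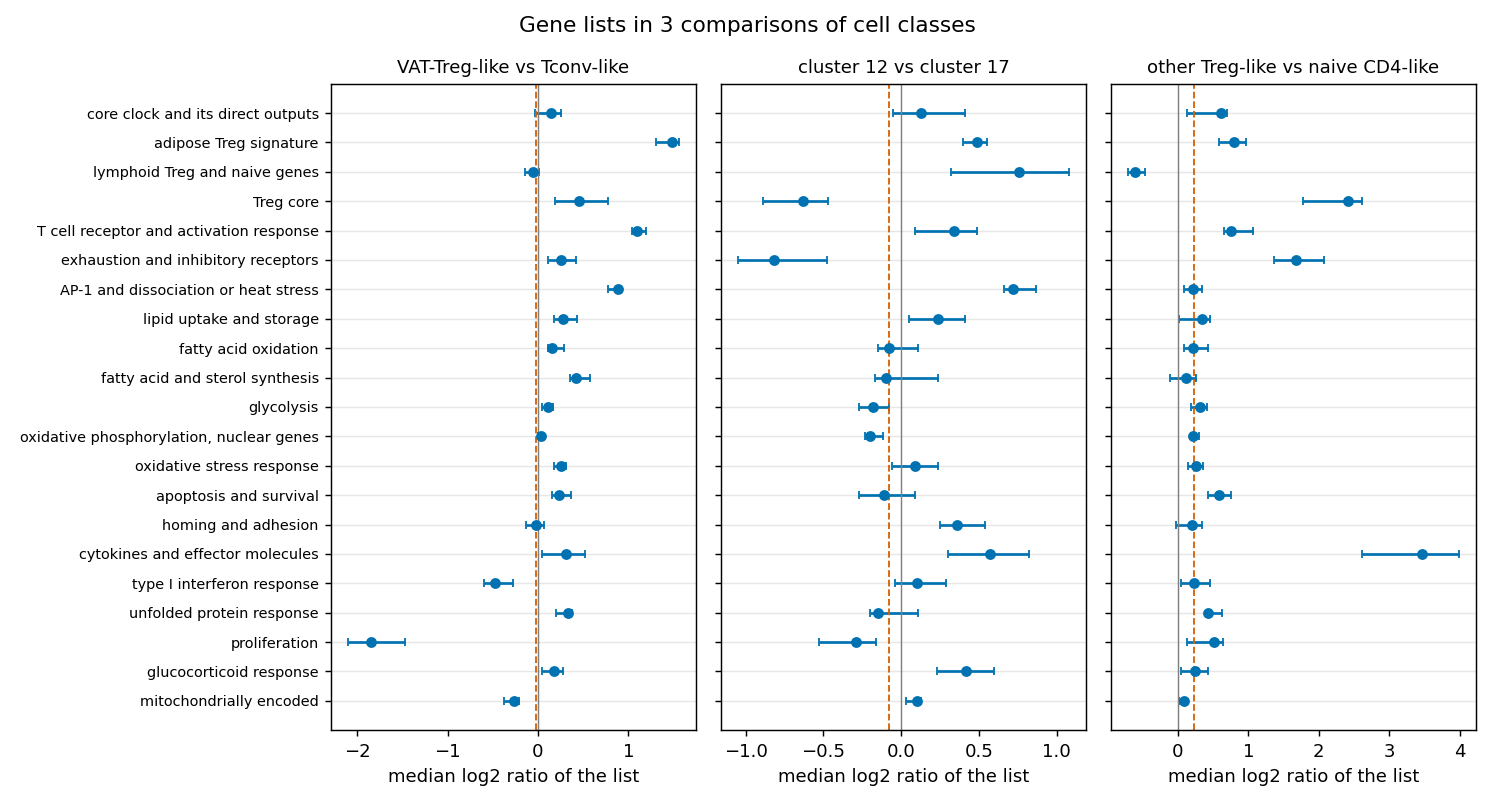
Median log2 ratio (x axis) of each fixed gene list (y axis) in the 3 comparisons, with 95% intervals from Poisson draws; the grey line marks 0 and the dashed line the median of all genes. In the VAT-Treg-like against Tconv-like panel the adipose Treg signature lies at 1.48 and the clock list at 0.14.

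The VAT-Treg-like clusters were compared with each other to see how far Tregs of this type differ among themselves. Cluster 12 had the highest Il1rl1 and cluster 17 the highest Cxcr3 of the Treg-like clusters (1726 and 630 cells of hashtags 1 to 4; 6205193 and 2198822 UMIs; 7642 genes, median log2 ratio -0.08). Arntl was higher in cluster 12 by 1.14 (0.84 to 1.27; 25.7 against 10.1 CPM), in all 4 hashtags. This rests on 159 UMIs in cluster 12 and only 25 in cluster 17. Its 95% counting interval over pooled counts, 0.56 to 1.84, is wider than the range over hashtags. Hlf was higher in cluster 12 by 1.45 (0.47 to 2.03), and Bhlhe40 (-0.71, -0.91 to -0.49) and Tef (-0.57, -1.97 to -0.12) were lower. Csnk1e was below 0 in all 4 hashtags (-0.22, -0.56 to -0.11), but its counting interval over pooled counts, -0.76 to 0.13, covers 0. Other measured clock genes changed sign between hashtags, with medians of 0.54 for Cry1, 0.42 for Per1, 0.23 for Csnk1d, 0.17 for Clock, 0.08 for Dbp and -0.15 for Nr1d2. As a whole the clock list stood at 0.13 (-0.05 to 0.41; percentile 95.5), with 7 of 12 members higher, and at -0.01 with the alternative hashtag rule. With the stricter cell filter 66.1% of the cells of cluster 17 fell in a cluster named Th1-like and 4.49% in the Treg-like cluster with the highest Cxcr3, so that comparison set other cells against cluster 12, and Arntl stood at -0.45.

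Cluster 12 carried more of the adipose signature (median 0.49, 0.40 to 0.55; 7 of 10 higher), with Ccr1 at 2.42 (1.89 to 2.55) and the interleukin-9 receptor gene Il9r at 1.10 (0.61 to 1.23), while Batf was lower at -1.10. It also had more of the interleukin-7 receptor gene Il7r (1.24, 1.17 to 1.47) and Ly6c1 (2.22, 1.93 to 2.72), members of the lymphoid and naive list (median 0.76, 0.32 to 1.08; 3 of 5 higher; -0.02 with the alternative hashtag rule). T cell receptor and activation genes split, with 6 of 12 higher in cluster 12 and 6 lower (median 0.34, 0.09 to 0.49; 0.21 without hashtag 3), and Cd69 at 1.39 (1.18 to 1.74) and Ier2 at 1.23 (1.16 to 1.40). AP-1 and dissociation genes were higher in 9 of 11 cases (median 0.72, 0.66 to 0.87; Junb at 1.09). Homing and adhesion genes were higher in 9 of 12 cases (median 0.36, 0.25 to 0.54), such as the gut homing genes Ccr9 (1.03) and Itgb7 (0.87), as were 7 of 9 cytokine genes (0.57, 0.30 to 0.82), among them Tnfsf11 (1.01) and Csf1 (0.69). All 9 glucocorticoid response genes had medians above 0 (0.42, 0.23 to 0.60), with Tsc22d3 at 0.73 and Fkbp5 at 0.44. Only 3 of the 9 were higher in all 4 hashtags, and the list median of single hashtags ran from -0.02 to 0.94. Lipid uptake genes were higher in 8 of 10 cases (0.24, 0.05 to 0.41), including Dgat1 (0.58). Cluster 17 had more of the Treg core genes Il2rb (-1.90), Icos (-0.63) and Entpd1 (-1.83), whose list median was -0.63 (-0.89 to -0.47; 4 of 5 lower). It also had more of the inhibitory receptor genes Pdcd1 (-0.82) and Entpd1, 2 of the 3 measured in that list (median -0.82, -1.05 to -0.48), while Tox changed sign between hashtags (0.20). Nuclear oxidative phosphorylation genes were lower in cluster 12 in 25 of 30 cases (median -0.20, -0.23 to -0.12), with Atp5g1 at -0.69 and Uqcrq at -0.51. Counts in this comparison are against 0. Of the 30 genes, 21 lay below the median of all genes (-0.08) and 15 were lower in all 4 hashtags. The remaining lists lay inside the middle 95% of random lists, from mitochondrially encoded genes at 0.10 to proliferation at -0.29. Between these were type I interferon at 0.10, oxidative stress at 0.09, fatty acid oxidation at -0.08, fatty acid and sterol synthesis at -0.10, apoptosis at -0.11, unfolded protein response at -0.15 and glycolysis at -0.18.

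Other Treg-like cells were set against naive CD4-like cells within hashtags 1, 5 and 6 (811 and 2576 cells; 2989019 and 10852933 UMIs; 7215 genes). The median of all genes was 0.23 here, so log2 ratios are read against that shift, and counts of higher genes are of those above it. In hashtags 5 and 6 the Treg-like side is mostly the larger cluster, led in part by interferon-induced genes. In hashtag 1 the smaller cluster gave 38 of the 60 Treg-like cells, so ranges over hashtags also hold a different mix of clusters. For each cluster alone only hashtags 5 and 6 had enough cells. Arntl was higher in the Treg-like cells by 0.82 (0.81 to 1.57; 19.2 against 9.53 CPM) in all 3 hashtags, as were Per1 (0.70, 0.69 to 0.89), Csnk1d (0.68, 0.59 to 0.73), Dbp (0.61, 0.29 to 0.82) and Bhlhe40 (1.99, 1.67 to 4.81). For Per1 (0.13 to 1.24) and Dbp (-0.01 to 0.76) the counting interval over pooled counts covers the shift. Arntl had 56 UMIs in the Treg-like and 87 in the naive cells, with a counting interval over pooled counts of 0.71 to 1.73. In hashtag 1 it had 5 UMIs in 60 Treg-like cells. The kinase gene Csnk1e was lower at -1 (-2.14 to -0.34), and Clock (0.19) and Cry1 (0.00) lay below the shift. The clock list stood at 0.61 (0.13 to 0.70; percentile 98.8) with 5 of 9 members higher. Leaving out a hashtag moved Bhlhe40 to 3.24 (without 5) and 3.40 (without 6), and Csnk1e to -1.57 (without 6). Arntl was at 0.52 in the larger Treg-like cluster alone and at 2.02 in the smaller, and the clock list at 0.52 and 0.49.

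The same Treg-like cells had more of all 5 measured Treg core genes beyond the defining markers (median 2.41, 1.78 to 2.62), with the interleukin-2 receptor beta gene Il2rb at 2.63 (2.56 to 2.74) and the ectonucleotidase gene Entpd1 at 3 (1.18 to 3.23). Activation genes were higher in 9 of 11 cases (0.75, 0.66 to 1.07; 1.13 without hashtag 6; 0.32 in the larger cluster alone), such as the costimulatory receptor gene Icos at 1.53 (1.29 to 1.84). All 4 inhibitory receptor genes were higher (1.67, 1.36 to 2.08), with Pdcd1 at 2.18 and Tox at 1.17, but the median was 0.30 in the larger cluster alone and 2.51 in the smaller. The medians of all 5 cytokine genes lay above the shift (3.47, 2.61 to 3.99), but only 4 genes were above 0 in every hashtag. Among these were Ebi3, which encodes a subunit of interleukin-35, at 3.76 (2.85 to 4.32) and Csf1 at 3.47 (3.21 to 4.23). Survival genes were higher in 14 of 16 cases (0.58, 0.42 to 0.75), with Bcl2a1b at 2.03. The 6 measured adipose signature genes were higher too (0.79, 0.58 to 0.96), with Batf at 1.17 and S100a4 at 1.03. That median was 1.46 without hashtag 5, 1.42 without hashtag 6 and 3.13 with the stricter cell filter. Unfolded protein response genes were higher in 13 of 13 cases (0.43, 0.41 to 0.63; Hspa5 at 0.65), as were 4 of 7 proliferation genes (0.51, 0.13 to 0.64; Mcm3 at 0.69, and 0.41 without hashtag 5). Lower in Treg-like cells were the naive and lymphoid genes Ly6c1 (-1.33), S1pr1 (-0.76) and Il7r (-0.61), with a list median of -0.61 (-0.71 to -0.47), while the other 2 of the 5 members lay above the shift. The other lists lay inside the middle 95% of random lists. They were lipid uptake at 0.34, glycolysis at 0.32, oxidative stress at 0.25, glucocorticoid response at 0.24, type I interferon at 0.23, AP-1 at 0.22, nuclear oxidative phosphorylation at 0.22, fatty acid oxidation at 0.21, homing at 0.20, fatty acid and sterol synthesis at 0.12 and mitochondrially encoded genes at 0.09.

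**Figure D4:**
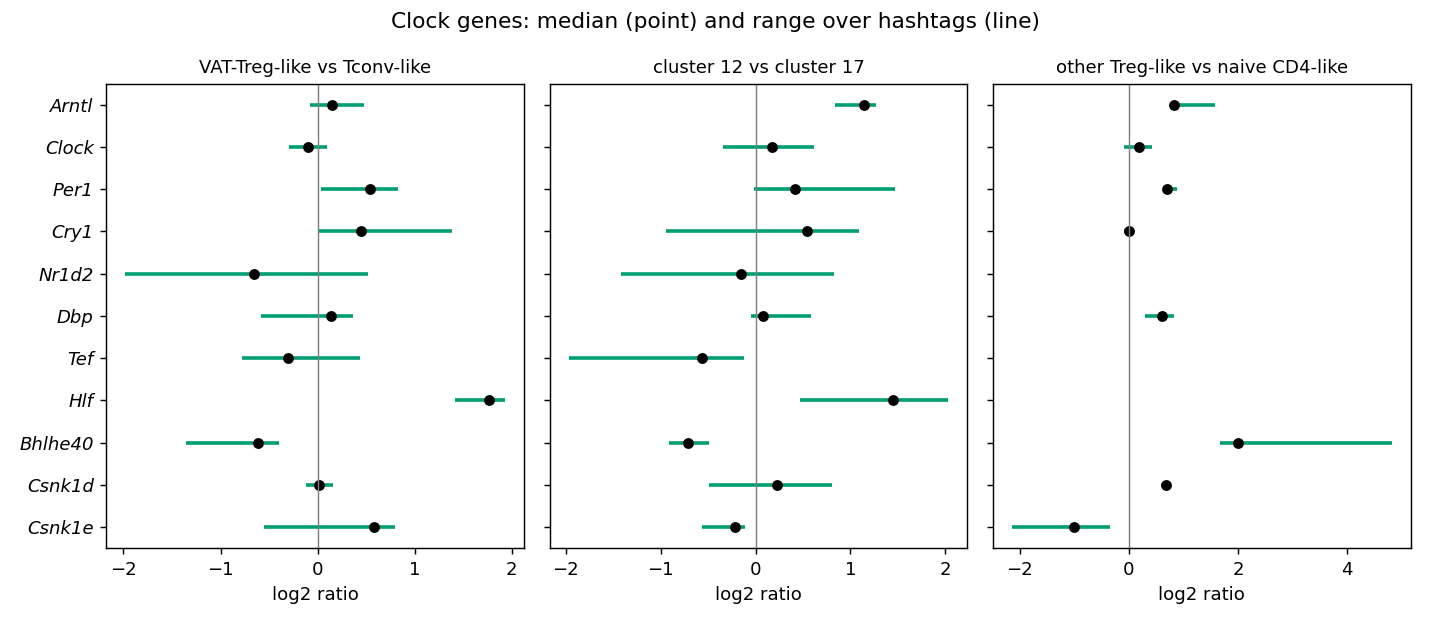
Log2 ratio (x axis) of clock genes (y axis) measured at 10 CPM or more in the 3 comparisons; points are medians and lines the range over hashtags. Arntl lies at 0.15 for VAT-Treg-like against Tconv-like cells, at 1.14 for cluster 12 against cluster 17, and at 0.82 for other Treg-like against naive CD4-like cells.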

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

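All tests in this part were chosen after the results were seen. Signals outside the data used for the comparisons were listed when they exceeded the 3 counts that a true 0 allows. The sorted CD4 library held 743 cells of non-T clusters, 5.46% of the cells kept. Hashtags 7, 8, 9 and 10 had 278, 10, 172 and 7 counts, against 560096 or more for each hashtag used. A further 86500 hashtag reads (1.83%) matched no tag, and 2269 barcodes had no hashtag call.

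The macrophage-like cluster (236 cells) carried T cell genes. The sum of Cd3e, Cd3d, Cd3g and Trac, which encode parts of the T cell receptor complex, was 10.6 UMIs per cell (10.2 to 11.1). Free T cell RNA alone would put it no higher than in the stromal-like cluster with the fewest such UMIs, 2.70 per cell (2.03 to 3.52), so the table argues against free RNA as the whole source. The level was 98.2% (94.4 to 102) of the 10.8 UMIs per cell in T cells, which a T cell in the same droplet would give, but the other stromal-like cluster reached 83.2% and erythroid-like cells 96.3%. The median of 3189 UMIs per cell, against 6172 in called doublets, goes against pairs of whole cells, so T cells with macrophage RNA or fragments stay open, and no biological explanation was tested.

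A T cell cluster of 838 cells had a median of 1069 UMIs per cell, against 3269 in the 12018 other T cells. Ribosomal protein genes made up 9.88% of its UMIs against 27.4%, a difference of -17.5 percentage points, which shallow sampling alone would not produce. Its median mitochondrial share was 5.71% against 2.14%, and the nuclear RNA Malat1 was at 101944 against 39569 CPM. This is consistent with damaged cells that lost cytoplasmic RNA. No biological explanation was tested.

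Some clock genes differed between hashtags in VAT-Treg-like cells. Counts of all 18 clock list genes at 5 CPM or more were thinned to equal depth and redrawn with Poisson error, which tends to widen differences. The median largest log2 difference was then 1.06 (0.86 to 1.33) in VAT-Treg-like cells and 0.77 (0.58 to 1) in Tconv-like cells. The gap of 0.29 (-0.01 to 0.63) leaves open a difference of the whole pool, such as in handling. Free RNA in the droplets was common to all hashtags, which shared the same expression library. Within cluster 12 alone the value was 102% (69.8 to 143) of that in all VAT-Treg-like cells. Counting error enters both values and can hold up this percentage, so it does not decide on a different mix of the VAT-Treg-like clusters. For Npas2, Cry1, Nr1d1 and Nr1d2, not at equal depth, the median was 3.48 (2.84 to 4.71) within cluster 12 and 2.73 (2.27 to 3.99) in all VAT-Treg-like cells. It was 1.075 (0.867 to 1.77) in Tconv-like cells, but these genes were picked for their spread in VAT-Treg-like cells. Time of day, genotype and differences between mice stay open as untested, because no hashtag is assigned to them, and no biological explanation was tested.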

How the results depend on the processing

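Leaving out hashtags, the changed Leiden resolutions for the lists and genes, pooling of counts, removal of the cells with the most UMIs, the other Tconv-like classes and single other Treg-like clusters were chosen after the data were seen. The rest were planned. For the Treg-like share and the clock lists, 33 of 44 alternative values lay within the interval of the reported value and 11 moved. For the other lists 488 of 640 did, 134 moved and 18 reversed, and for single genes 1148 of 1411 lay within the range over hashtags, 248 moved and 15 reversed. Unless stated otherwise, the cause was not tested. The tissue, genotype and time comparisons and their alternatives were not run, because the hashtag names do not give these. No paired analysis of tissues or genotypes was possible for the same reason. Cells with a Foxp3 UMI gave no value for cluster 12 against 17 or for other Treg-like cells, nor did resolution 1.5 for cluster 12 against 17 or resolution 0.5 for other Treg-like cells. Depth limits single clock genes, many of which had under 100 UMIs per hashtag and class.

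The Treg-like share of T cells (25.1%) was 29.3% with the alternative hashtag rule, 17.5% with the stricter cell filter, 19.1% and 19.9% at resolutions 0.5 and 1.5, and 23.1% to 28.6% as single hashtags were left out. With Tregs taken as T cells with a Foxp3 UMI it was 5.97%, a fall set by that rule, since most Treg-like cells have no Foxp3 UMI at this depth. The clock list of VAT-Treg-like against Tconv-like cells (0.14) ran from 0.08 to 0.21 over the other alternatives and from -0.01 to 0.16 as hashtags were left out. For cluster 12 against 17 (0.13) it ran from -0.02 to 0.14 and from 0.07 to 0.21. For other Treg-like against naive cells (0.61) it ran from 0.39 to 0.62 and from 0.45 to 0.70.

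The stricter cell filter put 66.1% of the cells of cluster 17 in a cluster named Th1-like, outside the VAT-Treg-like class. It reversed Treg core (-0.41), exhaustion (-0.08) and Acadvl (-0.04) in VAT-Treg-like against Tconv-like cells. For cluster 12 against 17 it reversed the lymphoid and naive list (-0.37), homing (-0.50), mitochondrially encoded genes (-0.27), Arntl (-0.45), Tef (0.22), Pdcd1 (0.22), Atp5g1 (0.19), Cycs (0.32) and Ccr4 (-0.50). Only 4.49% of the cells of cluster 17 were in the second cluster of that comparison then, so other cells were compared. For other Treg-like against naive cells, mitochondrially encoded genes (-0.17) and Creld2 (-0.86) reversed. Resolution 1.5 reversed Treg core (-0.66) and exhaustion (-0.38) in VAT-Treg-like cells. The alternative hashtag rule reversed Gzma in VAT-Treg-like against Tconv-like cells (0.33) and the lymphoid and naive list of cluster 12 against 17 (-0.02).

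In place of the VAT-Treg-like class, T cells of any cluster with a Foxp3 UMI were set against Tconv-like cells without one. This contrast of other cells reversed interferon response (0.01), proliferation (0.09), Icos (0.16), Ube2c (0.13) and Birc5 (0.08) of VAT-Treg-like against Tconv-like cells. Without the proliferating and low-UMI clusters, proliferation (0.22) and Birc5 (0.39) reversed. With Th1-like clusters as the other class, proliferation (0.20), Birc5 (0.47) and Gzma (0.68) did. As single hashtags were left out, Treg core ran from -0.02 to 0.74 and exhaustion from -0.05 to 0.56, and mitochondrially encoded genes of other Treg-like cells from -0.11 to 0.12.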

Other observations

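Nothing in this part was planned, and the genes named were chosen after their values were seen. Genes were ranked by spread between hashtags 1 to 4 in VAT-Treg-like cells, relative to counting error. The top ranks included an immediate early gene and a chemokine gene. Such ranks favour genes with many UMIs, since Malat1 ranked 11 with a largest log2 difference of only 0.12. The mix of the VAT-Treg-like clusters differed between hashtags, so values are given within cluster 12. Cxcl2, which encodes a neutrophil chemokine, was there at 1443, 2253, 792 and 1329 CPM in hashtags 1 to 4, and in Tconv-like cells of the same hashtags at 102, 320, 59.7 and 122 CPM. The AP-1 gene Fos was at 1708, 2814, 1496 and 2881 CPM in cluster 12, and the proprotein convertase gene Furin at 446, 658, 215 and 784 CPM. By spread relative to counting error among 9189 genes in VAT-Treg-like cells, Cry1 ranked 72, Npas2 79, Nr1d2 121 and Bhlhe40 170, while Arntl ranked 4013. In Tconv-like cells, which held more UMIs, Cry1 ranked 363 and Nr1d2 866 among 9386 genes.

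Arntl also differed between T cell clusters of the pooled library. It was at 8.22 CPM in naive CD4-like cells, 30.9 in Tfh-like cells and 39.2 in NKT or innate-like cells, beside 25.9 in cluster 12 and 11.3 in cluster 17. These values are pooled over hashtags, whose shares differ between clusters and whose Arntl levels differ in Tconv-like cells, so they are not within hashtags. Pparg, which encodes a regulator of VAT Tregs, was at 61.7 CPM (55.7 to 68.2) in cluster 12 and 51.7 (42.6 to 62.1) in cluster 17, against 2.26 (1.49 to 3.29) in naive CD4-like cells. Il10 was higher in cluster 17 (259 CPM, 238 to 281) than in cluster 12 (175 CPM, 165 to 186), whereas Areg was at 302 and 1817 CPM. Pparg, Il10 and Areg are among the markers that named both clusters VAT-Treg-like, so their levels in part restate that naming and the clustering. The vascular cluster of 273 cells carried 6.15 UMIs of the 4 T cell genes per cell, 56.8% of the level in T cells. A group of 16 cells was led by the mast cell protease genes Mcpt4, Cma1 and Cpa3, and a naive CD4-like group of 20 cells by the activation genes Egr1, Egr2 and Egr3.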
